A study of Homo sapiens with 8 samples.

How the data were processed

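RNA was profiled by high-throughput sequencing in A549 cells, a human lung adenocarcinoma line, in 8 libraries that the labels place in 4 groups of 2. Cells received 25 pmol of a scramble locked nucleic acid (LNA) gapmer, 25 pmol of an LNA gapmer against the long non-coding RNA LY6K-AS, 40 pmol of a scramble siRNA or 40 pmol of an siRNA against YWHAG. A gapmer is an antisense oligonucleotide that directs cleavage of its target RNA by RNase H. The LY6K-AS knockdown libraries are titled LNA1 and LNA3, so they may carry separate gapmers, and the YWHAG knockdown libraries si1 and si2, so they may carry separate siRNAs; the labels settle neither. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The siRNA control columns are numbered 2 and 3 in their table and 1 and 2 in the labels, so they were assigned to the group only and are named here by their table numbers.

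The deposited values were RPKM in 2 tables, the LNA libraries in one and the siRNA libraries in the other, normalized separately. STAR, featureCounts, Subread, Picard and the genome build hg38 are named per the submitters' processing notes, with no version, role or parameter, and strand use in counting is not given in the sources used here. The strand of a read could therefore not be used to tell overlapping antisense genes apart. Gene identifiers were matched to GENCODE release 29: 57055 of 66206 in each table matched by identifier, 52238 with the same version. The 9151 others were left out of the LNA table's tests, because no length was at hand to rescale them, and 116 of them had an RPKM of at least 0.5 in at least 2 libraries. In the siRNA table they stayed in.

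The divisor of each table's RPKM was found from the values. Only genes with the same identifier version were used for this. In the LNA table their deposited RPKM was multiplied by the genomic span of the gene, introns included. The products were whole multiples of 1 step per library for 100% of values within a tolerance of 0.05 reads, against 32.8 to 33.4% with merged exon length. In the siRNA table merged exon length gave 100% and genomic span 39.7 to 40.2%. The LNA values were therefore rescaled to RPKM per kilobase of merged exon length before any test, and the values as deposited were kept as an alternative. Matched genes of another version, among them RRM2, CDC6, GADD45A, RPS27A and LYNX1, were rescaled with lengths that were not checked in this way. Whether the LNA reads were counted over exons or over the whole span is not given. Rescaling changes the divisor and not the reads counted. The whole reads recovered in this way summed to 27.5 M, 24.6 M, 21.2 M and 24.7 M (M, 1e6 reads) in LNA controls 1 and 2 and LY6K-AS knockdowns 1 and 2, and to 28.7 M, 28.9 M, 28.6 M and 28.3 M in siRNA controls 2 and 3 and YWHAG knockdowns 1 and 2. At this depth 3 reads corresponded to 0.0868 to 0.115 RPM. Intervals on single genes are exact Poisson 95% intervals and cover counting error only, since reads without molecular identifiers are not independent molecules.

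Each knockdown was compared with its own scramble control in limma 3.58.1 (R 4.3.3) with an intensity trend on log2(RPKM + 1), over genes with an RPKM of at least 0.5 in at least 2 of the 4 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. With 2 libraries per group each fit had 2 residual degrees of freedom. The design was fixed before the data were examined, as were 29 gene lists holding 801 genes and the rule for the genes named. That rule takes the targeted genes, LY6K and all measured 14-3-3 genes; per direction the 8 genes with the largest change past the threshold whose knockdown libraries lie beyond both controls and whose higher mean is at least 2 RPKM, filled by smallest p where fewer pass; the 3 members with the smallest p of the kinetochore list, the spindle assembly checkpoint list and each list past the threshold; and, between the knockdowns, 5 genes with the smallest p. Pseudogenes, unnamed clone loci and small RNAs were left out of the genes chosen by size or by p. Genes said to lead a list are those with its smallest p, not its largest change. No gene passed, so all 8 per direction were filled by smallest p and are given as values that did not pass.

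Lists with at least 4 measured members, 26 in each comparison, were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists. Camera with a correlation estimated from the data and fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, were run beside it. With an estimated correlation camera tests on the residual degrees of freedom, here 2 per comparison, which leaves little room for any list to pass. A call lost there does not by itself show that a list's genes are correlated. The lists cover 14-3-3 genes, the LY6 locus on 8q24.3, the kinetochore, the spindle assembly checkpoint, the mitotic spindle and cytokinesis, G2/M regulators with cohesin and condensin, the anaphase-promoting complex, DNA replication, replication-dependent histones, p53 targets, interferon response, NF-kB and inflammatory genes, the integrated stress and unfolded protein response, heat shock, cholesterol synthesis, hypoxia and glycolysis, NRF2 targets, epithelial-mesenchymal transition and TGF-beta, apoptosis regulators, growth factor and MAPK feedback, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, and markers of RNA quality (mitochondrially encoded genes and long nuclear-retained RNAs) and of immune, fibroblast, endothelial, neuronal and lung epithelial cells. The mitotic, 14-3-3 and LY6 lists were chosen from the study's title and design, so their direction is not evidence independent of the study. The knockdowns were compared with each other across genes tested in both tables and in a limma fit of 4 group means over 8 libraries, in which each fold change is taken within its own table.

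LY6K-AS has no gene identifier in the labels. It was matched by position to LNCOC1, the annotated antisense gene that overlaps LY6K, and this match is an assumption.

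The test was checked on simulated reads drawn from the real genes' means and depths with a dispersion of 0.01, which leaves out the larger spread seen between the real knockdown libraries. Over 12601 genes of the LNA table, 80.0% of 100 genes changed by a log2 size of 1 and 97.0% of 100 changed by 2 were called, with 23 unchanged genes called. Over 11758 genes of the siRNA table these were 79.0%, 100% and 16. In each the shifted list was called and 0 of 25 unshifted lists were. The simulated genes were drawn independently, so this cannot check the preset correlation for lists whose genes move together. After LY6K-AS knockdown the estimated correlation was 0.43 for the kinetochore list and 0.91 for the checkpoint list. Replicates were compared for duplicates by a chi-square on recovered reads over genes with at least 20 reads, which was 9.34 per degree of freedom or more in each pair, so no pair was a single library deposited again.

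Other settings fixed with the design were pseudocounts of 0.1 and 0.5, no filter on low values, a mean RPKM of at least 2, libraries shifted to the same median, quantile normalization, no intensity trend, array weights, a log2 fold change of at least 1, a replicate block and leaving out each library. With a knockdown library left out, the spread comes from the controls alone. Chosen after seeing the data were the values as deposited, limma voom on the recovered reads, leaving out mitochondrially encoded genes, a spread pooled over 8 libraries (fitted to the 12861 genes tested in both tables), and removal from each library of a loess trend (span 0.5) on the GC content of each gene's longest transcript.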

Results

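RNA from A549 cells, a human lung adenocarcinoma line, was sequenced in 8 libraries: 2 each after transfection of a scramble LNA gapmer, an LNA gapmer against the antisense RNA LY6K-AS, a scramble siRNA and an siRNA against YWHAG, which encodes 14-3-3 gamma. The study's title places the work in lung adenocarcinoma and in mitotic progression. Reads recovered per library came to between 21.2 M and 27.5 M in the LNA group and between 28.3 M and 28.9 M in the siRNA group (M, 1e6 reads). The 2 tables were normalized separately, so the effects of the knockdowns were measured within a table.

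The first comparison asked what changed when LY6K-AS was depleted. LNCOC1 (ENSG00000253741.1, hg38 chromosome 8, 142702252 to 142726973, minus strand), the annotated antisense gene taken as LY6K-AS, had 34 and 17 reads in the LNA controls and 3 and 8 reads in the knockdown libraries. The ratio of knockdown to control was 0.244 after scaling for depth, with a 95% interval of 0.115 to 0.474 from counting error alone. LNCOC1 lay below the expression filter, and in the fit without a filter its log2 change was −0.14 ± 0.05 (SE), which did not pass (limma adjusted p = 0.336). The change was −0.82 and −0.26 with pseudocounts of 0.1 and 0.5, and over all settings it ran from −0.03 (values as deposited) to −1.97 (voom), lower in each. Without LNA control 1 it was −0.09. LY6K (ENSG00000160886.13, chromosome 8, 142700111 to 142705127, plus strand), the protein-coding gene on the opposite strand, had 35 and 42 reads in the controls and 53 and 55 in the knockdown libraries, a ratio of 1.59 (1.17 to 2.15), with a log2 change of 0.18 ± 0.09 that did not pass (limma adjusted p = 0.487). LY6K and LNCOC1 overlap, and strand use in counting is not given, so reads in the overlap cannot be told apart.

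**Figure D1:**
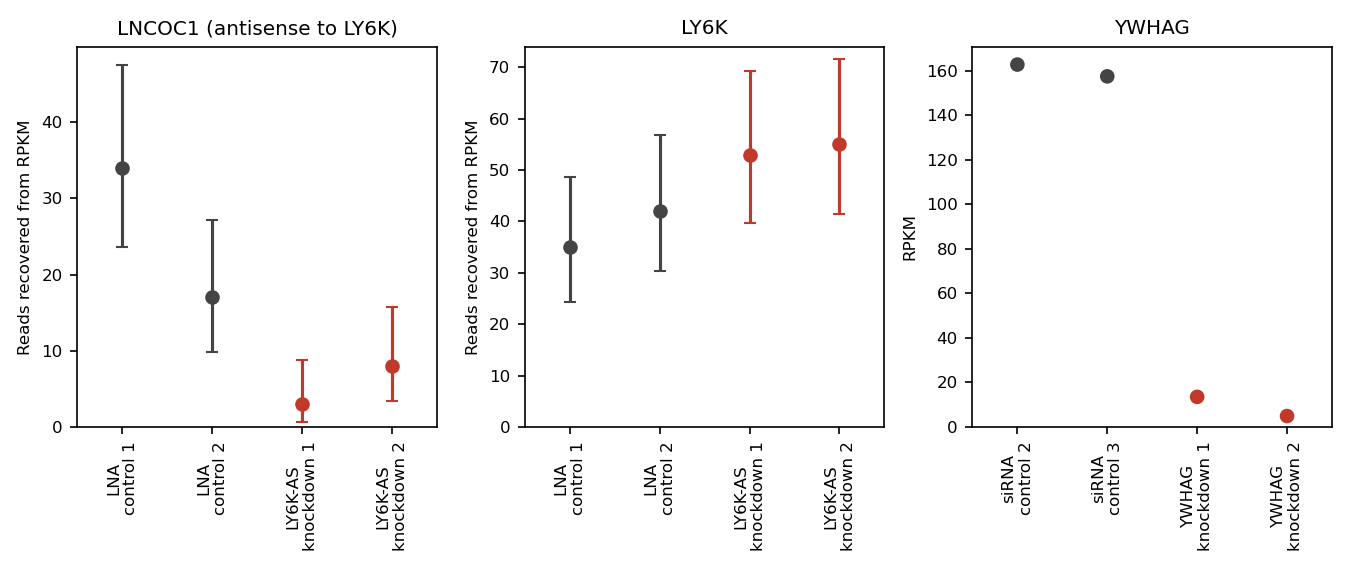
Targeted genes in each library: reads recovered for LNCOC1 and LY6K with exact Poisson 95% intervals (counting error only), and YWHAG in RPKM. Each point is 1 library, dark for control and red for knockdown; LNCOC1 had 34 and 17 reads in the controls against 3 and 8, and YWHAG 163 and 158 RPKM against 13.5 and 4.91.

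After LY6K-AS knockdown, genes of mitosis and DNA replication were lower together. Of 36 measured kinetochore genes, whose products attach chromosomes to spindle microtubules, 35 were lower, with a median log2 change of −0.81 (camera adjusted p = 6.5e-17, a call lost at adjusted p = 0.454 with an estimated correlation). The medians were −0.65 and −1.01 in knockdown libraries 1 and 2, in which mitochondrially encoded genes took 10.4% and 5.16% of reads (10.4% and 7.99% in the controls). The kinetochore subunits SPC25 (3.99 ± 0.0136 to 1.37 ± 0.0921 RPKM, mean ± SD, n = 2) and CENPU (8.12 ± 0.304 to 3.23 ± 0.117) had the smallest p in the list, followed by ZWINT (52.4 ± 0.684 to 26.4 ± 1.76). All 18 spindle assembly checkpoint genes were lower (median −0.89, camera adjusted p = 1.2e-09, and adjusted p = 0.460 with an estimated correlation), among them the mitotic kinases BUB1 (log2 change −1.25 ± 0.18 SE) and AURKB (−1.02 ± 0.15) and the chromosomal passenger subunit CDCA8 (−1.11 ± 0.16).

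The wider cell-cycle lists were lower in camera at the preset correlation, and each of these 4 calls was lost at adjusted p = 0.454 with an estimated correlation. That correlation was 0.84 for the spindle, 0.60 for the G2/M, 0.29 for the replication and −0.01 for the anaphase-promoting complex list. The mitotic spindle and cytokinesis list had 29 of 30 members lower (median −1.01, camera adjusted p = 6.5e-17), led by NUSAP1 (−1.12), KIF2C (16.3 ± 0.307 to 7.68 ± 0.787 RPKM) and SPAG5 (−0.94). All 32 G2/M regulators and cohesin or condensin genes were lower (median −0.95, camera adjusted p = 1.7e-19), including PTTG1, which encodes securin (29.4 ± 0.586 to 13.5 ± 0.460 RPKM), the condensin subunit NCAPG and the cyclin-dependent kinase subunit CKS2. All 45 DNA replication genes were lower (median −0.69, camera adjusted p = 1.7e-19), among them RRM2, the small subunit of ribonucleotide reductase (48.1 ± 0.899 to 19.4 ± 1.06 RPKM), the licensing factor CDC6 (21.3 ± 0.0108 to 11.1 ± 0.159) and the clamp loader subunit RFC4. The anaphase-promoting complex list shifted less (median −0.20, 14 of 16 lower, camera adjusted p = 0.00816), with ANAPC1 at −0.50, CDC23 at −0.45 and FBXO5, an inhibitor of the complex, at −0.75.

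Counted with p adjusted over the list alone, 29 kinetochore, 15 checkpoint, 29 spindle, 29 G2/M and 38 replication genes fell and 0 of the anaphase-promoting complex. Adjusted over all genes tested, 0 of each fell, with 31, 15, 29, 31, 39 and 6 at an unadjusted p under 0.05. Of all genes tested, 25.3% had such a p in either direction. On the values as deposited, an alternative chosen after seeing the data, the kinetochore median was −0.40, the checkpoint −0.61, spindle −0.64, G2/M −0.66, replication −0.46 and anaphase-promoting complex −0.13. Over the alternatives the adjusted p of these 6 lists ran from 5.2e-28 to 0.460. Across the 14662 genes the log2 change rose with transcript GC content (Spearman rho 0.53, 0.41 and 0.52 in knockdown libraries 1 and 2, and 0.24 for control 2 minus control 1; genes are not independent replicates). Kinetochore transcripts averaged 43.3% GC; with the GC trend removed from each library, an alternative chosen after seeing the data, the kinetochore median was −0.73 and the 6 lists kept their calls.

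Targets of p53 and NF-kB were higher as groups. All 28 p53 targets were higher (median 0.73, camera adjusted p = 3.4e-12, and adjusted p = 0.454 with an estimated correlation), with medians of 0.53 and 0.88 in knockdown libraries 1 and 2, whose mitochondrially encoded genes had medians of 0.11 and −0.89. CDKN1A, the cyclin-dependent kinase inhibitor p21 (ENSG00000124762.13, chromosome 6, 36676460 to 36687339), went from 59.4 ± 0.512 to 196 ± 54.2 RPKM (mean ± SD, n = 2), GADD45A from 15.3 ± 0.672 to 41.4 ± 10.3 and TP53INP1 from 1.96 ± 0.0888 to 5.64 ± 0.948. Of 21 NF-kB and inflammatory genes 19 were higher (median 0.58, camera adjusted p = 5.6e-06, and adjusted p = 0.454 with an estimated correlation), led by the NF-kB subunit RELB (11.1 ± 0.285 to 27.7 ± 1.14 RPKM), BIRC3 (5.74 ± 0.00997 to 11.6 ± 1.54) and TNFAIP3, a feedback inhibitor of NF-kB (1.68 ± 0.126 to 3.53 ± 0.152). Adjusted over the list alone, 20 p53 targets and 10 NF-kB genes rose; adjusted over all genes 0 did, with 25 and 11 at an unadjusted p under 0.05. Both calls were thus lost with an estimated correlation, while fry gave the NF-kB list an adjusted p of 0.0499 and the p53 list 0.0742. Over the alternatives the adjusted p of the 2 lists ran from 4.7e-16 to 0.454. With the GC trend removed the medians were 0.70 and 0.49 and both calls stood.

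The 14-3-3 genes, a family of phosphoserine-binding adaptors, did not move together. SFN, which encodes 14-3-3 sigma, was higher in both knockdown libraries (162 ± 2.80 to 293 ± 2.09 RPKM, log2 change 0.85 ± 0.09 SE). The other 6 were lower: YWHAE −0.50, YWHAZ −0.46, YWHAH −0.32, YWHAQ −0.32, YWHAG −0.31 and YWHAB −0.28, with YWHAG at 143 and 145 RPKM in the controls and 133 and 101 after knockdown. None passed over all genes (limma adjusted p from 0.103 for SFN to 0.291 for YWHAG); adjusted over the list alone 3 fell and 1 rose, with 5 of the 7 at an unadjusted p under 0.05. The list's median was −0.32 (camera adjusted p = 0.0404, or adjusted p = 0.578 with an estimated correlation; range over alternatives 0.00797 to 0.578). Its call was lost without LNA control 1 (median −0.32), without LNA control 2 (−0.32), without knockdown 2 (−0.23) and with the GC trend removed (−0.24).

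Around the target, 6 of 7 measured genes of the LY6 locus were higher (median 0.37, camera adjusted p = 0.0139, and adjusted p = 0.499 with an estimated correlation; range over alternatives 0.00392 to 0.526). LYNX1, a modulator of nicotinic receptors, stood at 0.973 ± 0.0854 and 2.49 ± 0.222 RPKM in control and knockdown, LY6E at 7.49 ± 0.172 and 11.5 ± 1.75, and THEM6 at 14.6 ± 1.08 and 19.1 ± 1.46. Here 2 genes rose when adjusted over the list alone, and 0 over all genes, with 4 at an unadjusted p under 0.05. These transcripts averaged 61.5% GC. The list's call was lost without knockdown 2 (median 0.24) and with the GC trend removed (median 0.05).

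**Figure D2:**
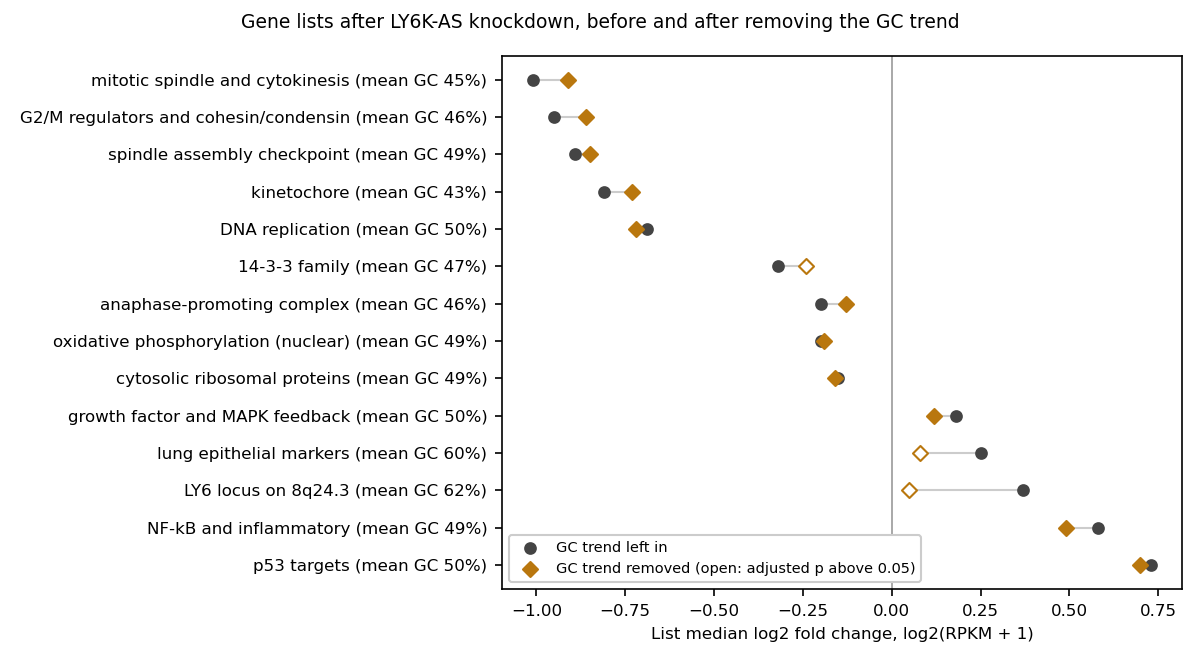
List medians after LY6K-AS knockdown with the GC trend left in (circles) and removed from each library (diamonds), for the 14 lists past the threshold; the horizontal axis is the median log2 fold change. Open diamonds mark the lists that no longer passed: 14-3-3 genes (−0.24), lung epithelial markers (0.08) and the LY6 locus (0.05).

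Smaller shifts were seen in other groups after LY6K-AS knockdown, and none of these 4 calls held with an estimated correlation. Of 74 cytosolic ribosomal protein genes 59 were lower (median −0.15, camera adjusted p = 1.8e-05, and adjusted p = 0.454 with an estimated correlation), with RPS27A at −0.70, RPL34 at −0.49 and RPS15A at −0.49. Of 56 nuclear-encoded oxidative phosphorylation genes 44 were lower (median −0.20, camera adjusted p = 3.0e-05, and adjusted p = 0.460 with an estimated correlation), with the complex I subunits NDUFB8 at −0.54, NDUFB6 at −0.45 and NDUFA12 at −0.44. The share of reads from mitochondrially encoded genes was 10.4% and 7.99% in the controls and 10.4% and 5.16% in knockdown libraries 1 and 2. Growth factor and MAPK feedback genes were higher (median 0.18, 17 of 25, camera adjusted p = 0.0348, and adjusted p = 0.454 with an estimated correlation), led by FOSL1 (0.67), DUSP4 (0.52) and PHLDA1 (0.44). Lung epithelial markers were higher (median 0.25, 11 of 12, camera adjusted p = 0.0180, and adjusted p = 0.460 with an estimated correlation, mean GC 59.8%), with keratin 19 (KRT19) at 38.4 ± 1.33 and 103 ± 23.4 RPKM, the surfactant lipid transporter ABCA3 at 0.87 and FOXA1 at 0.30. Of these 4 lists 0, 0, 3 and 1 members passed when adjusted over the list alone, and 0 over all genes, with 17, 20, 9 and 3 at an unadjusted p under 0.05. Of all genes tested, 25.3% had such a p, a share near that of the ribosomal and lung epithelial lists. Over the alternatives the adjusted p of the 4 lists ran from 5.6e-08 to 0.460. The growth factor call was lost without LNA control 1 (median 0.15) and without knockdown 2 (0.06), and its median was 0.30 without knockdown 1. The lung epithelial call was lost without knockdown 2 (0.15) and with the GC trend removed (0.08), and its median was 0.42 without knockdown 1.

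The remaining lists did not pass after LY6K-AS knockdown, so that 14 of the 26 tested lists passed. Replication-dependent histones had a median of 0.39 (camera adjusted p = 0.0662), passed without LNA control 1 (0.41), and were at 0.25 without LNA control 2 and 0.24 without knockdown 2. Apoptosis regulators had a median of 0.15 (camera adjusted p = 0.110, fry 0.0499), interferon response genes 0.11, the integrated stress and unfolded protein response 0.08, neuronal markers 0.12, hypoxia and glycolysis −0.03 and heat shock genes −0.10. Epithelial-mesenchymal transition and TGF-beta genes had a median of −0.18, and passed without knockdown 1 (−0.41). Mitochondrially encoded genes had a median of −0.40, with 0.11 and −0.89 in knockdown libraries 1 and 2, passed without LNA control 2 (−0.59) and without knockdown 1 (−0.89), and stood at −0.21 without LNA control 1. Without knockdown 2 the epithelial-mesenchymal and mitochondrially encoded lists turned direction (0.08 and 0.11). Without knockdown 1 the hypoxia, heat shock and cholesterol lists turned direction (0.05, 0.01 and −0.05). In knockdown libraries 1 and 2 taken alone, the stress response had 0.02 and 0.18, interferon genes 0.10 and 0.07, heat shock genes −0.20 and 0.01, hypoxia genes −0.09 and 0.05, NRF2 targets −0.03 and −0.07, cholesterol genes 0.08 and −0.05, and neuronal markers 0.18 and −0.02. Without LNA control 1 the stress, heat shock, hypoxia and cholesterol medians were 0.05, −0.06, −0.06 and 0.02, and without LNA control 2 the hypoxia median was −0.00. Median, mean and test differed in sign for NRF2 targets (median −0.11, mean 0.08, test lower), cholesterol synthesis (median −0.00, mean 0.03, test higher) and long nuclear-retained RNAs (median 0.16, mean 0.12, test lower). The last turned direction in the test when any library but knockdown 2 was left out (medians 0.19, 0.13 and 0.01), and its median was −0.03 without knockdown 2. Too few markers of other cell types were measured for a test: 3 immune (median 0.20), 3 fibroblast (median −0.10, mean 0.28) and 0 endothelial genes.

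Over single genes, limma called 0 of 14662 after LY6K-AS knockdown (smallest adjusted p 0.103), with 3706 at an unadjusted p under 0.05, 1988 higher and 1718 lower. limma voom on the recovered reads called 0 of 12601, with 3338 at an unadjusted p under 0.05. The 8 higher genes with the smallest p, each with an adjusted p of 0.103 and both knockdown libraries above both controls, were RELB (log2 change 1.24), IRAK2, a kinase of interleukin-1 receptor signalling (1.19), TBC1D2 (1.16), the trypsinogen gene PRSS3 (1.13), SH2D5 (1.09), LZTS3 (1.08), FBXO44 (0.94) and the p53-induced long non-coding RNA PURPL (0.93). The 8 lower genes, also at 0.103, were RRM2 (−1.27), NCAPG (−1.21), the chromatin protein HMGB2 (−1.16), the phosphatase CDKN3 (−1.14), CENPU (−1.11), SPC25 (−1.08), PTTG1 (−1.06) and CKS2 (−0.98). Lying beyond both controls was a condition for naming these genes, and 62.0% of all genes tested did so in 1 direction or the other. Reads could be shared with overlapping genes for PRSS3 (UBE2R2-AS1), FBXO44 (FBXO2), CENPU (PRIMPOL), NCAPG (LCORL), RFC4 (EIF4A2), CDKN1A (DINOL), CDC23 (KIF20A) and RRM2 (AC007240.1), and PRSS3 also has near-identical paralogs. With the spread pooled over all 8 libraries, an alternative chosen after these counts were seen and fitted to the 12861 genes tested in both tables, 64 genes passed (25 higher, 39 lower), among them CDKN1A, GADD45A, TP53INP1, SFN, RRM2, BUB1, AURKB, NCAPG and PTTG1. The count was 7725 without knockdown 1 and 4350 without knockdown 2, where the lone knockdown library is assumed to vary like the controls, and 0 without either control; across genes the SD of the log2 difference between libraries was 0.16 for the controls and 0.40 for the knockdowns.

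The LY6K-AS knockdown libraries, which may carry separate gapmers, were compared with each other without a test, since each stands alone. Differences from the control mean in knockdown libraries 1 and 2 shared their sign for 71.6% of 14662 genes (Pearson r 0.56, Spearman rho 0.58 across genes). Both libraries are measured against the same controls, and simulated unchanged libraries gave r 0.33. The simulation gave control and knockdown libraries the same spread, which fixes its r near that value whatever the data. The real SD between libraries was 0.16 for the controls and 0.40 for the knockdowns, so 0.33 is not a matched reference. The covariance was 0.0878 against 0.0144 simulated. With each knockdown library set against a different control r was 0.52 or 0.48. The same measures in the YWHAG knockdown libraries, titled si1 and si2 and perhaps separate siRNAs, were lower. There r was 0.40, with a covariance of 0.0626 against 0.0185 simulated, and r was 0.32 or 0.33 with a different control each. The simulated r, 0.33 here too, assumes shared controls and equal spread. It is no reference for values with a different control each, and the SDs were 0.19 for controls and 0.43 for knockdowns. The sign was shared for 65.4% of 13903 genes. RRM2 stood near the same level in both (20.2 and 18.7 RPKM), as did SPC25 (1.43 and 1.30) and RELB (26.9 and 28.5), whereas CDKN1A was at 158 and 234 RPKM and KRT19 at 86.9 and 120.

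The second comparison asked what changed when YWHAG was depleted. YWHAG (ENSG00000170027.6, chromosome 7, 76326794 to 76359031, minus strand) stood at 163 and 158 RPKM in the siRNA controls and 13.5 and 4.91 RPKM in YWHAG knockdown libraries 1 and 2, a log2 change of −4.12 ± 0.43 (SE) and a change in mean RPKM of −94.2%, with an adjusted p of 0.130 in limma that did not pass over all genes. The change was between −3.47 and −4.77 when any library was left out, and passed with the spread pooled over 8 libraries (adjusted p 0.0109; range over alternatives 0.0109 to 0.999). LNCOC1 had 35 and 30 reads in the controls and 14 and 42 in the knockdowns, and LY6K had 11 and 18 against 23 and 4.

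The other 14-3-3 genes were lower or near the control level after YWHAG knockdown, and with YWHAG itself all 7 lay below it. SFN went from 89.9 ± 5.40 to 54.8 ± 5.83 RPKM (mean ± SD, n = 2; log2 change −0.71 ± 0.14 SE), YWHAQ from 259 ± 5.49 to 169 ± 56.0 (−0.65 ± 0.25), and YWHAZ stood at 117 and 114 RPKM in the controls and 72.6 and 107 after knockdown (−0.39 ± 0.22). YWHAH (−0.21), YWHAE (−0.16) and YWHAB (−0.05) had smaller differences, and YWHAH was at 0.04 without knockdown 2. None passed over all genes. Adjusted over the list alone 2 fell, with 3 at an unadjusted p under 0.05, YWHAG included. The list was not tested without YWHAG, so its call does not speak for the other genes alone. The list, which holds the target itself, had a median of −0.39 (camera adjusted p = 0.0148, and adjusted p = 0.683 with an estimated correlation; range over alternatives 0.00264 to 0.683), and −0.67 without knockdown 2.

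Most cytosolic ribosomal protein genes were higher after YWHAG knockdown. Of 74 measured, 70 were higher (median 0.33, camera adjusted p = 7.7e-17, a call lost at adjusted p = 0.262 with an estimated correlation), with medians of 0.31 and 0.34 in knockdown libraries 1 and 2. The estimated correlation was 0.00, below the preset 0.01, so this loss does not show correlated members. That estimate rests on 2 residual degrees of freedom, and it was 0.11 for the same list after LY6K-AS knockdown, so correlated members are not excluded. RPL23A went from 106 ± 1.44 to 171 ± 0.0703 RPKM, RPS2 from 311 ± 20.2 to 457 ± 21.2 and RPS29 from 23.8 ± 1.48 to 35.0 ± 0.838. No member rose when adjusted over the list alone, nor over all genes, with 31 at an unadjusted p under 0.05, and the list had an adjusted p of 0.0672 by fry. Its median was 0.21 with quantile normalization, and the range over its alternatives was 1.6e-19 to 0.262. Ribosomal protein genes have many processed pseudogenes, and RPL23A and RPS2 hold small nucleolar RNA genes, so reads may be shared.

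Mitotic genes were slightly lower after YWHAG knockdown, and each of the 4 calls was lost at adjusted p = 0.683 with an estimated correlation. Of 37 kinetochore genes 30 were lower (median −0.19, camera adjusted p = 0.0368), of 18 checkpoint genes 16 (−0.22, 0.0366), of 30 spindle and cytokinesis genes 28 (−0.30, 6.7e-04) and of 32 G2/M genes 28 (−0.25, 0.00707). CENPF, a kinetochore-associated protein, went from 30.8 ± 4.52 to 18.5 ± 2.09 RPKM, and AURKB, MAD2L1BP, SGO2, RACGAP1, KIF2C, KIF18A, FOXM1 and CCNB1 had log2 changes between −0.34 and −0.61. SKA2, which stabilises kinetochore-microtubule attachment, went the other way (13.7 ± 0.323 to 25.7 ± 4.52 RPKM, log2 change 0.85 ± 0.17 SE), as did the condensin subunit NCAPD2 (25.6 and 22.9 RPKM in the controls, 36.1 and 34.4 after knockdown). In each list 0 genes passed when adjusted over the list alone and 0 over all genes, with 6, 3, 5 and 6 at an unadjusted p under 0.05; over their alternatives the range was 4.6e-06 to 0.938. Of all genes tested, 16.4% had an unadjusted limma p under 0.05, a share near that of these lists. The kinetochore call was lost without either siRNA control (medians −0.19 and −0.21 without 2 and 3) and without knockdown 1, where the median was still lower (−0.11) and only the sign of the test changed. The checkpoint call was lost without siRNA control 2 (−0.17) and knockdown 1 (−0.15), and the G2/M call without siRNA control 2 (−0.18) and knockdown 1 (−0.20). The spindle median was −0.19 without siRNA control 2.

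Stress and metabolic lists were also higher in camera at the preset correlation, and each of these 4 calls was lost at adjusted p = 0.683 with an estimated correlation. Integrated stress and unfolded protein response genes had a median of 0.21 (19 of 27 higher, camera adjusted p = 0.00707), led by the lipoprotein receptor VLDLR (log2 change 1.08 ± 0.14), the cystine transporter SLC7A11 (16.0 ± 0.530 to 29.3 ± 2.85 RPKM) and HERPUD1 (0.62). Hypoxia and glycolysis genes had a median of 0.25 (21 of 27, camera adjusted p = 0.00707), with GAPDH at 0.56, BNIP3 at 0.65 and PFKFB3, an activator of glycolysis, lower at −0.59. Targets of p53 had a median of 0.13 (18 of 28, camera adjusted p = 0.0366), with FAS at 0.56, CDKN1A at 0.47 and GADD45A at 0.35, and lung epithelial markers 0.41 (9 of 11, camera adjusted p = 0.0188), with KRT7 at 0.77, KRT18 at 0.37 and FOXA1 at −0.78. In these lists 2, 0, 0 and 0 genes passed when adjusted over the list alone, and 0 over all genes, with 7, 4, 2 and 3 at an unadjusted p under 0.05. Of all genes tested, 16.4% had such a p. Over their alternatives the adjusted p ran from 1.4e-06 to 0.683. The stress list's call was lost without knockdown 2 (0.15), and its median was 0.34 without knockdown 1 and 0.35 without siRNA control 3. The hypoxia call was lost without knockdown 1 (0.03), with 0.52 without knockdown 2. The p53 call was lost without siRNA control 2 (0.13) and knockdown 2 (0.03), with 0.23 without knockdown 1. The lung epithelial call was lost without siRNA control 2 (0.28) and knockdown 1 (0.09). In all, 10 of 26 lists passed after YWHAG knockdown, and 5 without siRNA control 2.

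The YWHAG knockdown libraries, whose titles leave open whether they carry separate siRNAs, differed from each other in several lists that did not pass. Interferon response genes had medians of 0.38 and −0.61 in knockdown libraries 1 and 2, NF-kB genes 0.17 and −0.62, and each list passed, in opposite directions, when either library was left out. In those fits the spread comes from the controls alone, whose SD (0.19) was below that of the knockdowns (0.43), so these passes do not test the difference between the libraries. Epithelial-mesenchymal transition and TGF-beta genes had 0.52 and −0.29, replication-dependent histones 0.49 and −0.11 (0.04 in both, 0.07 without siRNA control 3), NRF2 targets −0.34 and 0.04 and DNA replication genes −0.41 and 0.04; these 4 lists passed without knockdown 2 (0.52, 0.49, −0.34 and −0.41) and turned direction without knockdown 1, and DNA replication also passed without siRNA control 3 (−0.24). The LY6 locus had a median of 0.28 and passed without knockdown 2 (0.41), with 0.11 without knockdown 1. Cholesterol synthesis genes had 0.05 and passed without siRNA control 3 (0.15) and knockdown 1 (0.05), with 0.01 without siRNA control 2 and 0.00 without knockdown 2, and nuclear-encoded oxidative phosphorylation genes had 0.04, with −0.01 without knockdown 2, and passed without knockdown 1 (0.08). Heat shock genes had −0.17 (−0.27 and −0.10 in knockdown libraries 1 and 2), apoptosis regulators −0.06 (0.02 and −0.27, and −0.17 without siRNA control 2) and neuronal markers 0.19 (−0.07 and 0.27). Long nuclear-retained RNAs had 0.05, with 0.12 and 0.02 without siRNA controls 2 and 3 and 0.21 and 0.33 without knockdowns 1 and 2. The anaphase-promoting complex had −0.04 (−0.15 without knockdown 2), and its test turned direction without siRNA control 2 (−0.07) and knockdown 1 (−0.02). Median and test differed in sign for growth factor genes (median −0.00, mean −0.02, test higher; −0.02 and 0.01 without siRNA controls 2 and 3, −0.07 and 0.12 without knockdowns 1 and 2) and mitochondrially encoded genes (median −0.02, mean −0.01, test higher). The latter passed without siRNA control 3 (0.13) and turned without siRNA control 2 (−0.17) and knockdown 2 (−0.11), with 0.11 without knockdown 1; their share of reads was 18.3%, 21.8%, 16.9% and 21.7% in siRNA controls 2 and 3 and knockdowns 1 and 2. For 2 immune and 2 fibroblast markers the medians were −0.68 and −0.16, with 0 endothelial markers measured.

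Over single genes, limma called 0 of 13903 after YWHAG knockdown (smallest adjusted p 0.130), with 2281 at an unadjusted p under 0.05, 1044 higher and 1237 lower, and voom called 0 of 11758, with 1940. The 8 higher genes with the smallest p, each at 0.130, were the neutrophil chemokine CXCL5 (16.3 and 19.0 RPKM in the controls, 126 and 86.2 after knockdown), the lysine methyltransferase SETD7 (log2 change 1.84 ± 0.15 SE), LCLAT1, an acyltransferase of cardiolipin remodelling (1.66), GNPNAT1 (1.62), the pyruvate dehydrogenase component PDHX (1.61), RP2 (1.39), the DNA repair protein NBN (1.29) and C12orf73 (1.23). Besides YWHAG, the lower genes at 0.130 were ACTL8 (2.71 ± 0.0213 to 0.424 ± 0.0150 RPKM, −1.38), the chondroitin synthase CHSY1 (−1.32), ZNF239 (−1.31), the cytidine deaminase APOBEC3B (−1.14), the prostaglandin receptor PTGER2 (−1.13), DACT2 (−1.12) and MARVELD1 (−1.10). PDHX overlaps APIP, C12orf73 overlaps HSP90B1 and APOBEC3B overlaps APOBEC3A, so reads could be shared. With the spread pooled over 8 libraries, over the same 12861 genes, 214 passed (140 higher, 74 lower), among them SETD7, LCLAT1, CXCL5, ACTL8, CHSY1, SFN and YWHAG. Leaving out any library left 0 genes; the SD of the log2 difference between libraries was 0.19 for the controls and 0.43 for the knockdowns, and the change did not follow GC content across genes (rho 0.03).

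**Figure D3:**
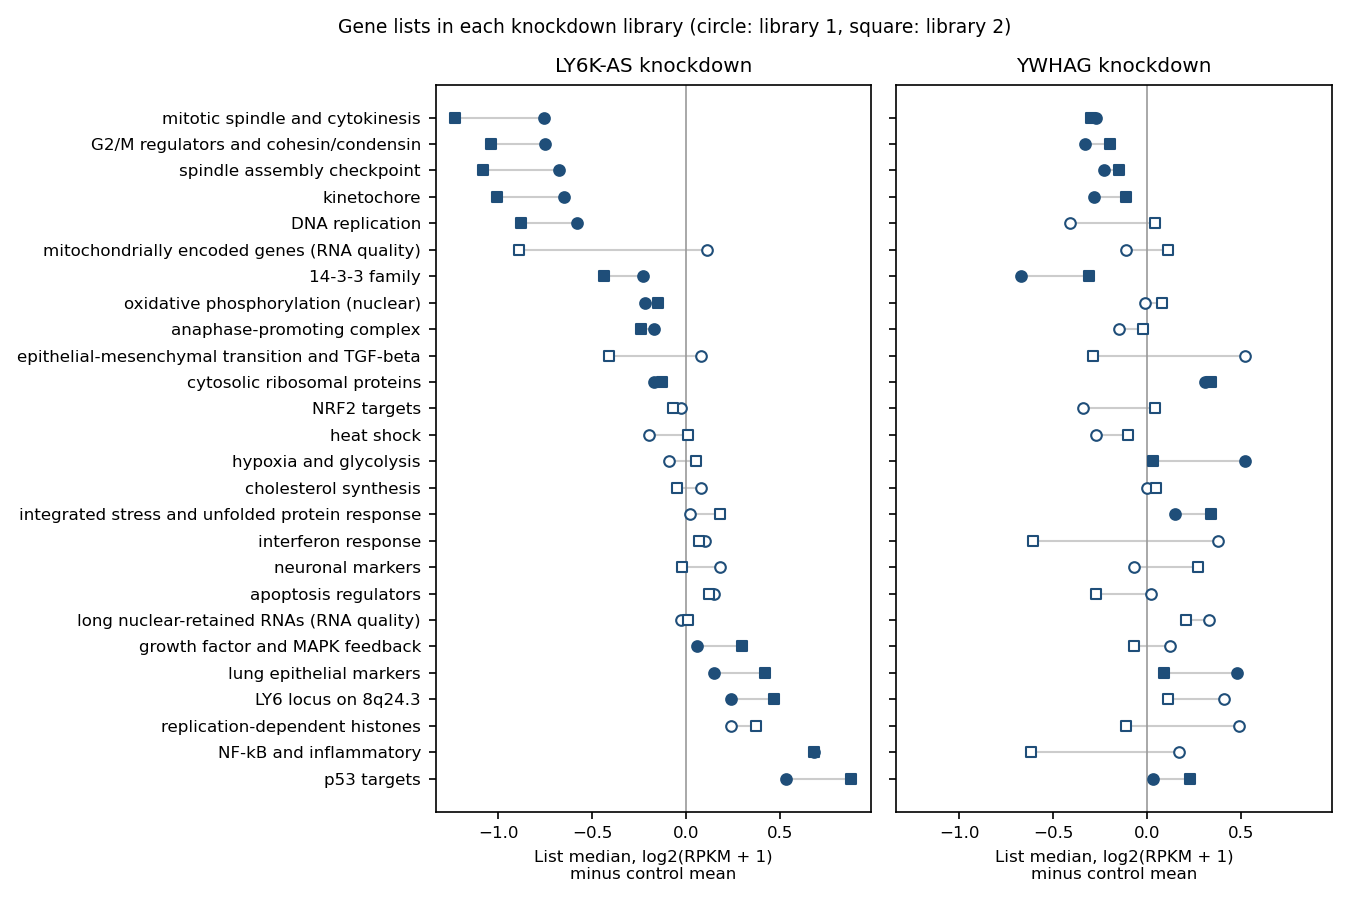
Median log2 difference from the control mean of each tested gene list in knockdown library 1 (circles) and 2 (squares) after LY6K-AS knockdown (left) and YWHAG knockdown (right); filled symbols mark lists past a camera adjusted p of 0.05 at the preset correlation. The kinetochore medians were −0.65 and −1.01 on the left and −0.28 and −0.11 on the right, and the ribosomal protein medians −0.17 and −0.13 against 0.31 and 0.34.

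The last comparison set the knockdowns side by side. The log2 changes of 12861 genes tested in both tables, which share no control library, correlated weakly across genes (Pearson r 0.10, Spearman rho 0.11, same sign for 54.0%; genes are not independent replicates). The r was −0.00 without YWHAG knockdown 1, 0.04 without siRNA control 2 and 0.16 without siRNA control 3 or YWHAG knockdown 2. At an unadjusted p under 0.05 in both, 115 genes were higher in both against 122 for independent lists and 161 lower in both against 146 (Fisher's exact test, two-sided, p = 0.545 and 0.179). With the pooled spread 0 genes shared a direction and 3 were called in opposite directions, of which SFN is a 14-3-3 gene.

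SFN differed between the knockdowns, higher after LY6K-AS depletion (0.85) and lower after YWHAG depletion (−0.71), a difference of 1.56 ± 0.17 (SE, limma adjusted p = 0.0443). It was among 23 of 12861 genes called for a difference, 6 with the higher change after LY6K-AS knockdown and 17 with the lower, and 2623 had an unadjusted p under 0.05; voom called 18. Leaving out small RNAs, pseudogenes and clone loci, which took out SNORD69 and AC245041.1, the 5 with the smallest p were LCLAT1 (−0.34 against 1.66), ACTL8 (difference 1.49 ± 0.14), SETD7 (−1.84 ± 0.18), TAF9B (−1.58 ± 0.16) and the glycosyltransferase GALNT2 (−1.47 ± 0.16), each with a limma adjusted p of 0.0208 to 0.0437. The count was 0 with a replicate block on the LNA libraries, where the calls of SFN and of these 5 genes ended, and 0 without LNA control 1 or 2, LY6K-AS knockdown 2 or siRNA control 2 or 3, and 1185, 718 and 735 without LY6K-AS knockdown 1 and YWHAG knockdowns 1 and 2.

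Among the lists, the difference passed in camera for the mitotic and replication lists, lower after LY6K-AS knockdown (kinetochore median −0.81 against −0.20, camera adjusted p = 5.1e-10), for p53 targets (0.73 against 0.13, 1.5e-06) and NF-kB genes (0.58 against −0.13, 7.8e-04), higher after LY6K-AS knockdown, and for ribosomal proteins (−0.15 against 0.33, 2.0e-19). In camera with an estimated correlation the adjusted p was 0.473 for the kinetochore, spindle and G2/M lists and 0.483 for the checkpoint and DNA replication lists. It was 0.473 for p53 targets, 0.573 for NF-kB genes and 0.133 for ribosomal proteins, so none passed. By fry the ribosomal list had an adjusted p of 0.00406. Whether multi-mapped or intronic reads were counted alike in the 2 tables is not known. The separately normalized control means were 21.7 and 120 RPKM for YWHAE and 43.3 and 116 for YWHAZ. This limits ribosomal and 14-3-3 changes set side by side. The 14-3-3 list did not differ in the test (−0.32 against −0.39, camera adjusted p = 0.341), nor did the 5 LY6 locus genes tested in both (0.24 against 0.28, camera adjusted p = 0.969).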

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

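The test of LY6 locus genes after YWHAG knockdown was chosen after that value was seen, and so were the removal of the GC trend from each library and the condition that the 1 Mb window hold once GC is removed; the other tests were written down first.

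The change differed between the knockdowns for 10 gene lists in camera at the preset correlation, and for 0 of them adjusted with an estimated correlation, while the ribosomal list also passed by fry. The median difference, LY6K-AS minus YWHAG knockdown, was −0.55 for kinetochore genes, −0.65 for the spindle assembly checkpoint, −0.73 for the mitotic spindle and cytokinesis, −0.65 for G2/M regulators and cohesin or condensin, and −0.52 for DNA replication. It was 0.62 for p53 targets, 0.71 for NF-kB and inflammatory genes, −0.29 for hypoxia and glycolysis, −0.48 for cytosolic ribosomal proteins and −0.20 for nuclear-encoded oxidative phosphorylation. The LNA gapmer and the siRNA were given with different scramble controls and doses, so the oligonucleotide type is confounded with the target in these differences.

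The lower kinetochore genes after LY6K-AS knockdown were set against 3 technical explanations. Low GC content of the transcripts is argued against as the whole cause, since the list median was −0.73 (SE 0.06) with the GC trend fitted outside the list removed, against −0.81 before. With the trend on merged exon length removed the median was −0.84, but that trend was weak across genes (rho −0.11), so this decides little. A change in 1 library alone is argued against by a median of −0.65 in the weaker library. A lower share of dividing cells, an effect of LNA1 and LNA3 on other transcripts and an effect of LY6K-AS itself stay open, and no value here separates them. The pattern may be biological, as a hypothesis found and tested on the same libraries.

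The higher ribosomal protein genes after YWHAG knockdown kept a median of 0.39 (SE 0.03) with the GC trend removed and 0.36 (SE 0.03) with the exon length trend removed, against 0.33 before. The weaker library's median was 0.31. The library medians argue against 1 library as the whole cause. Across genes the change hardly followed GC content (rho 0.03) or merged exon length (rho −0.07), so removing these trends could move the median little. The values thus argue only against such trends across genes. The length of each gene's main mRNA was not tested. Reads shared with processed pseudogenes were not tested and stay open beside a biological change, which these data suggest only as a hypothesis.

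The higher LY6 locus genes after LY6K-AS knockdown are a pattern that followed GC content, and whether that trend is technical was not tested. Removing the GC trend took the list median from 0.37 to 0.05 (SE 0.11) and ended the call because the change itself was smaller, which goes with GC content as its source. After YWHAG knockdown the 5 measured genes of the list had a median of 0.28 (0.41 and 0.11 in libraries 1 and 2) and did not pass (camera adjusted p = 0.0669); the median was 0.32 with the GC trend removed, in a comparison that did not follow GC content across genes (rho 0.03). A change not specific to LY6K-AS goes with that direction, and GC content does not account for it there, so specificity stays open. All 25 tested genes within 1 Mb of LNCOC1 had a median of 0.37, at the 98.34 percentile of windows of as many neighbouring genes, but at the 62.7 percentile with a median of 0.03 once GC was removed; these genes averaged 62.2% GC against 49.9% over all genes, so a local effect and GC content cannot be told apart here.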

How the results depend on the processing

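Choices made after seeing the data were the deposited span scale, voom, leaving out mitochondrial genes, the pooled spread and the GC correction; the others were planned. Single genes: the 0 calls became 64 after LY6K-AS and 214 after YWHAG knockdown with the pooled spread, which changed both the degrees of freedom and the genes tested (12861), and YWHAG itself passed there (−4.12). Without 1 library the LY6K-AS count ran from 0 to 7725 and the YWHAG count stayed at 0. The targets kept their direction (LNCOC1 −0.19 to −0.09, YWHAG −4.77 to −3.47 without 1 library). Lists: 0 passed in either comparison with an estimated correlation; without 1 library 10 to 16 passed after LY6K-AS and 5 to 15 after YWHAG knockdown. The difference between knockdowns, 23 genes, became 5 with no filter, 56 with a mean RPKM of at least 2, 38 with quantile normalization, 36 with array weights, 5 without mitochondrial genes and 43 on the deposited scale, and 0 to 1185 without 1 library; the similarity r ran from −0.00 to 0.16. The agreement r of the LY6K-AS libraries was 0.50 with a pseudocount of 0.1, 0.52 with no filter, 0.60 with a mean RPKM of at least 2, 0.47 with the GC trend removed, and 0.56 to 0.59 without 1 control. The cause was not tested for these.

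Test directions turned, mostly near 0. After LY6K-AS knockdown: long nuclear-retained RNAs with quantile normalization (0.13), array weights, the block or pooled spread (0.16) and GC removal (0.31); heat shock with GC removal (0.06); NRF2 targets (−0.07) and cholesterol synthesis (−0.05) by voom, the latter also on the deposited scale (−0.01); neuronal markers with no filter (0.00). After YWHAG knockdown: the anaphase-promoting complex with a mean RPKM of at least 2, array weights, voom or pooled spread (−0.04) and with median or quantile scaling (−0.00); growth factor genes with no filter (−0.00), quantile scaling (0.02) and voom (−0.12); interferon genes with no filter (0.02); mitochondrially encoded genes with quantile scaling (−0.02); YWHAB with GC removal (0.00). Without 1 library, lists that turned had medians, after LY6K-AS knockdown, from 0.01 to 0.19 (long nuclear-retained RNAs, −0.03 without knockdown 2), 0.01 (heat shock, −0.20 in the other library), −0.05 (cholesterol), 0.05 (hypoxia), 0.08 (epithelial-mesenchymal, −0.41) and 0.11 (mitochondrially encoded, −0.89). After YWHAG knockdown, with the other library's value second, they were 0.04 and −0.41 (DNA replication), 0.04 and −0.34 (NRF2 targets), 0.04 and −0.46 (the gene YWHAH), 0.17 and −0.62 (NF-kB), 0.38 and −0.61 (interferon), −0.29 and 0.52 (epithelial-mesenchymal), −0.11 and −0.28 (kinetochore), −0.11 and 0.49 (histones), −0.07 and 0.27 (neuronal), −0.07 and 0.12 (growth factor) and 0.02 and −0.27 (apoptosis). The anaphase-promoting complex turned at −0.07 without siRNA control 2 and −0.02 without knockdown 1, with −0.15 in knockdown library 1. Mitochondrially encoded genes turned at −0.17 without siRNA control 2 and −0.11 without knockdown 2, with 0.11 in knockdown library 2. The cause was not tested. Of the other values for lists, 342 and 300 kept their direction and side of the threshold after LY6K-AS and YWHAG knockdown, libraries left out aside. Another 29 and 18 lost a pass, those with an estimated correlation included, and 5 and 6 gained one.

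The LNA libraries share only a number between groups (the correlation of same-numbered deviations was 0.08); with the replicate block 0 genes and 16 lists passed after LY6K-AS knockdown and 0 genes for the difference, against 23. For the siRNA libraries, no paired analysis was possible because their control columns carry no replicate number from the labels. Depth limits LNCOC1 and LY6K, with at most 55 reads in an LNA library.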

Other observations

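Small nucleolar and small nuclear RNA genes had lower medians than protein-coding genes after YWHAG knockdown, and processed pseudogenes a higher one. Of 101 small nucleolar RNA genes above the filter 25.7% were higher (median log2 change −0.23), and of 67 small nuclear RNA genes 31.3% (median −0.27), against 40.9% of 11320 protein-coding genes (median −0.06) and 61.5% of 506 processed pseudogenes (median 0.09). The 89 miRNA genes (42.7% higher, median −0.11) and 74 genes annotated as miscellaneous RNA (39.2%, −0.11) lay near protein-coding genes. After LY6K-AS knockdown the medians of the first 4 classes were −0.05, −0.05, −0.00 and −0.02. These classes were not tested, and how fully these libraries capture small RNAs is not known.

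GC content marked the LY6K-AS comparison across the whole transcriptome. Genes with the lowest GC content (under 42.5%) had a median log2 change of −0.16 and those with the highest (over 57.0%) 0.28, against −0.04 and −0.01 for the lowest and highest in the YWHAG comparison. The difference between the knockdown libraries also followed GC content (rho 0.31, library 2 minus library 1).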
